A study of Homo sapiens with 15 samples.

How the data were processed

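RNA from 15 A549 xenograft tumours was analysed, 5 in each of 3 groups (no stress, stress, post-stress), with groups and replicate numbers taken from the sample titles. Per the labels RNA was extracted with TRIzol and libraries were made with the Fast RNA-seq Lib Prep Kit V2. The deposited table holds raw gene counts of all 15 libraries for 60649 human and 56941 mouse genes. According to the submitters' processing notes, the authors made these counts by trimming reads with Trimmomatic (0.39), aligning them with HISAT2 (2.2.1) to the human build hg38 and the mouse build mm10, and counting them with featureCounts (2.0.6). The notes also name DESeq2 and edgeR, whose output is not used here. The strandedness of the kit, the annotation release, and whether reads were aligned to both genomes at once are not given in the sources used here. Levels of antisense genes and of near-identical gene copies are therefore uncertain, and mouse reads from conserved sequence can have been counted on human genes. No row of the table named anything other than a gene.

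Counts were split by species. The mouse share is the sum of mouse counts divided by all counts of a library. Total counts per library ranged from 16729091 to 19680449, human counts from 12877165 to 15892705 and mouse counts from 2119772 to 5937694. Genes were filtered with filterByExpr of edgeR, which left 15435 human genes with 99.8% of human counts and 13522 mouse genes with 99.4% of mouse counts. Within each species counts were scaled with TMM, and all 15 libraries entered a single edgeR quasi-likelihood fit with robust dispersions (edgeR 4.0.16, limma 3.58.1, R 4.3.3). The biological coefficient of variation was 0.187 for human and 0.308 for mouse genes. The 3 comparisons were stress against no stress, post-stress against no stress, and stress against post-stress. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called changed. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM are TMM-scaled within the species.

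Human symbols came from the reference table of gene names (60463 of 60649 identifiers) and coordinates from GENCODE 29. Mouse genes had no symbols in the references used, so that the 28 mouse lists, the score of M2-type minus M1-type macrophage genes and the mouse share without mitochondrial-encoded genes were not run, and mouse genes are given by identifier. Fixed before the data were examined were 22 lists of human genes: glucocorticoid response, cyclic AMP and beta-adrenergic response, immediate early genes, hypoxia response, glycolysis, oxidative phosphorylation, S phase and DNA replication, mitosis and G2/M, p53 targets, unfolded protein and ATF4 response, NRF2 targets, cholesterol synthesis, interferon response, NF-kB and inflammatory genes, macrophage-attracting and macrophage-acting ligands, epithelial-mesenchymal transition, epithelial junctions, antigen presentation, alveolar and airway secretory genes, ribosomal proteins, mitochondrial-encoded genes, and leukocyte and stroma genes not expected in A549. Lists with at least 5 tested members were tested with camera of limma on log2 CPM (prior count 2, preset correlation 0.01). A list score is the mean log2 CPM of its tested members. Adjustment over a list alone covers only the tested members of that list, with no correction across lists or comparisons. Members of a list can vary together, so that such counts of members are not separate observations.

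Genes were named by a rule written before the data were examined. It takes the 8 largest increases and decreases per comparison among called genes with a symbol and a logCPM of at least 1, up to 4 members per list by smallest p, up to 8 genes called against no stress in both restrained groups, and FKBP5, TSC22D3, PER1, CCL2, CSF1, IL34, VEGFA and MKI67. Some genes that the rule names are not reported here. Mouse shares were compared with exact 2-sided permutation tests. Shared controls were examined by the covariance of fold changes in the data, in simulated unchanged groups with the same controls, and with the controls split. Alternatives were DESeq2 size factors, DESeq2's Wald test (1.42.0), limma-voom, no filter (at least 1 count over all libraries), a CPM of at least 1 in 5 libraries, only the groups compared in the fit, the replicate number as a replicate block, the mouse share as a covariate, a log2 fold change of at least 1, camera with an estimated correlation, fry, and leaving out each library. Chosen after seeing the data was the fit without no-stress replicates 1 and 5.

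The procedure was tested on simulated data with the means and spread of all 15 libraries, in which 200 genes per species were changed in the stress group. Of human genes changed 1.5-fold, 2-fold and 3-fold, 37.3%, 64.2% and 89.4% were recovered, with 4 false calls of 131. For mouse genes these were 7.46%, 38.8% and 83.3%, with 6 false calls of 92. Both simulated changed lists were called and none of the 20 unchanged lists. The simulated genes varied independently of each other. This therefore does not test the list calls where members of a list vary together. Replicates were checked for duplicated libraries, and no pair of the 30 pairs within groups differed by counting noise alone (smallest chi-square per degree of freedom 12.0 for human and 6.60 for mouse counts).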

Results

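RNA was sequenced from 15 subcutaneous tumours that A549 cells, an established human lung adenocarcinoma line, formed in BALB/c nude mice, which lack mature T cells. In the no-stress group (n = 5) the mice were not restrained. In the stress group (n = 5) the labels give restraint, a standard psychological stressor of rodents, 7 days before transplantation. In the post-stress group (n = 5) they give restraint 12 days after transplantation. The labels do not say whether these numbers are durations or starting days. The 2 restrained groups therefore differ in when, and perhaps in how long, the animals were restrained. Each tumour gave 1 library, and reads were counted on human genes, which stand for the transplanted cells, and on mouse genes, which stand for host cells in the tumour piece. Total counts per library ranged from 16729091 to 19680449, human counts from 12877165 to 15892705 and mouse counts from 2119772 to 5937694. The series title names chronic stress, macrophage polarization and lung cancer progression. The comparisons ask how restraint before or after transplantation changed expression in the tumour cells and in the host cells around them.

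The share of counts on mouse genes varied widely within groups and did not separate them. It was 22.6% ± 6.65 (SD, n = 5) without stress, 21.0% ± 2.34 (SD, n = 5) with stress and 17.6% ± 4.93 (SD, n = 5) with post-stress. Stress differed from no stress by −1.53 percentage points (exact permutation p = 0.619, adjusted p = 0.619). The differences were −4.95 points for post-stress against no stress (exact permutation p = 0.206, adjusted p = 0.310) and 3.42 points for stress against post-stress (exact permutation p = 0.190, adjusted p = 0.310). These tests were 2-sided and the smallest p they allow is 0.00794. The highest shares were those of replicates 1 and 5 of the no-stress group, with 30.2% in replicate 1. Transcripts of the human mitochondrial genome took 4.25% ± 0.170 (SD, n = 5) of human counts without stress, 3.40% ± 0.564 with stress and 4.02% ± 0.369 with post-stress. The difference of −0.856 points for stress had an exact permutation p of 0.0397, which did not pass after adjustment over the 3 comparisons (adjusted p = 0.119).

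**Figure D1:**
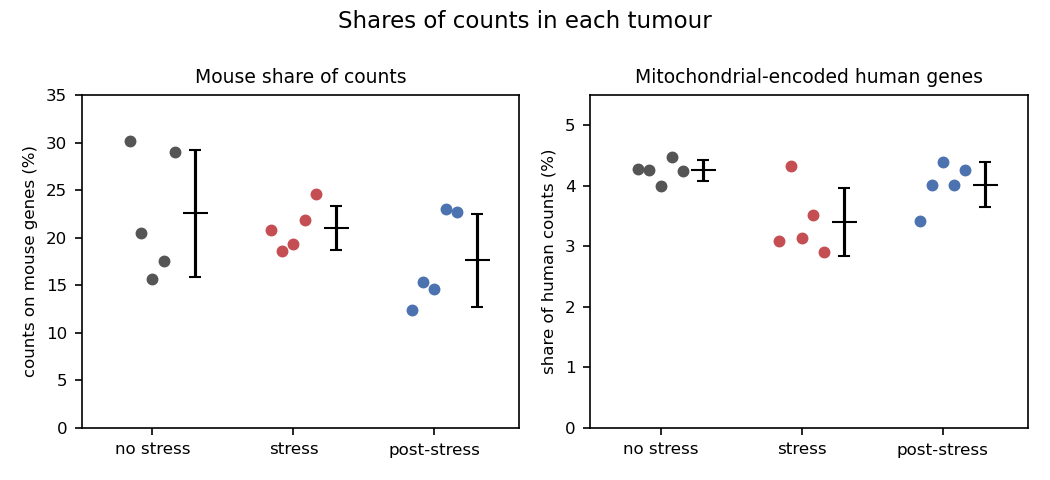
Share of all counts that fell on mouse genes (left, percent) and share of human counts on mitochondrial-encoded genes (right, percent) in each of 15 tumours. Points are single tumours, 5 per group, and the horizontal mark with its bar is the mean ± SD; the mouse shares overlap between groups, from 15.6% to 30.2% without stress, 18.6% to 24.6% with stress and 12.4% to 23.0% with post-stress.

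The comparison of stress with no stress asks what differed in tumour cells of animals for which the labels give restraint 7 days before transplantation. Whether the restraint went on after transplantation is not given. Expression of 1613 of 15435 tested human genes changed, 807 upward and 806 downward (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 211 of the higher and 32 of the lower genes changed at least 2-fold. Genes with large increases included IGFBP1, a secreted insulin-like growth factor binding protein induced by glucocorticoids and low insulin, which rose 5.23-fold from 73.0 ± 20.1 to 382 ± 27.9 CPM (counts scaled to library size; SD, n = 5; log2 fold change 2.39, SE 0.22, adjusted p = 1.02e-04). IGFBP5, which encodes another binding protein of this family, rose 12.7-fold from a low level of 1.09 ± 1.12 to 13.6 ± 6.97 CPM (adjusted p = 0.00919). DEPP1 rose 9.80-fold (adjusted p = 0.00168) and AKAP12, a scaffold protein that binds protein kinase A, 4.88-fold (adjusted p = 0.00467). Large decreases were fewer and smaller in CPM. MYCN, a transcription factor of the MYC family, fell from 11.6 ± 7.68 to 2.93 ± 1.25 CPM (log2 fold change −1.98, adjusted p = 0.0388), and the long non-coding RNA LINC00488 from 4.24 ± 0.941 to 1.38 ± 0.431 CPM (adjusted p = 0.00401). CCDC190 fell from 31.7 ± 12.7 to 12.96 ± 3.16 CPM (adjusted p = 0.0155) and GPA33 from 5.49 ± 2.45 to 2.31 ± 0.831 CPM (adjusted p = 0.0187). In all 5 stress tumours the CPM of each of these 8 genes lay on the same side of the no-stress mean. As they were picked for large changes in the same data, this adds no support. All 5 lay beyond every no-stress tumour for IGFBP1, IGFBP5, DEPP1, AKAP12 and LINC00488, 4 for MYCN and CCDC190 and 2 for GPA33. The smallest adjusted p of the comparison belonged to ZMYND8, a chromatin reader (39.9 ± 3.09 to 70.8 ± 4.55 CPM, adjusted p = 4.14e-05), followed by the neuronal-type glycolytic enzyme ENO2 (63.7 ± 9.76 to 163 ± 19.9 CPM, adjusted p = 5.81e-05). The call of MYCN ended in 9 of the 15 fits that left out 1 library (adjusted p up to 0.108), and that of GPA33 ended without no-stress replicate 3 (adjusted p = 0.0653). That of CCDC190 ended with replicate number as a block in the fit (adjusted p = 0.0596).

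Among genes known to respond to glucocorticoids, the adrenal stress hormones, 13 of 22 tested members of the list rose, 1 fell and 8 did not pass (18 rose and 1 fell when adjusted over the list alone). FKBP5, a co-chaperone of the glucocorticoid receptor and a standard readout of its activity, rose from 101 ± 13.6 to 214 ± 87.7 CPM (2.11-fold, adjusted p = 0.0284) and TSC22D3, which encodes the glucocorticoid-induced leucine zipper, from 80.1 ± 15.3 to 156 ± 54.7 CPM (1.95-fold, adjusted p = 0.0330). The phosphatase DUSP1 rose 4.00-fold (adjusted p = 0.0106). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 5.46-fold (adjusted p = 0.00595) and the metallothionein MT1X 3.96-fold (adjusted p = 0.00421). The thiamine transporter SLC19A2 fell (0.630-fold, adjusted p = 0.00759). PER1, a clock gene that glucocorticoids induce, stood at 13.6 ± 10.6 and 41.6 ± 20.1 CPM and did not pass (adjusted p = 0.0840). The median log2 fold change of the list was 0.83, and its members were on average higher than the genes outside it (camera adjusted p = 4.60e-12, or 0.0696 with an estimated correlation). The calls of FKBP5 and TSC22D3 were lost in 5 and 7 of the 15 fits that left out 1 library (adjusted p up to 0.0701 and 0.0852). Metallothionein genes are near-identical copies of each other, so that the count of MT1X is uncertain.

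Immediate early genes, transcription factors and phosphatases switched on within minutes of a stimulus, were higher as a group, with 10 of 16 members up and none down (median log2 fold change 1.32; camera adjusted p = 4.08e-10, or 0.0696 with an estimated correlation; 14 up and 1 down adjusted over the list alone). EGR1 rose from 7.95 ± 1.71 to 35.7 ± 9.72 CPM (4.48-fold, adjusted p = 0.00245), FOS from 26.2 ± 9.09 to 106 ± 39.6 CPM (4.05-fold, adjusted p = 0.00625) and JUNB 1.90-fold (adjusted p = 0.00700). Of 15 genes that respond to cyclic AMP and beta-adrenergic signalling, 5 rose and none fell (12 and 0 adjusted over the list alone; median 1.31; camera adjusted p = 4.49e-07, or 0.0824 with an estimated correlation). They included NR4A3, an orphan nuclear receptor (2.82-fold, adjusted p = 0.0239), the stress-responsive factor ATF3 (3.88-fold, adjusted p = 0.0332) and PCK1, the gluconeogenic enzyme, which went from 0.911 ± 0.818 to 7.29 ± 4.46 CPM (adjusted p = 0.0267). The calls of NR4A3, ATF3 and PCK1 ended in 3, 5 and 3 of the 15 fits that left out 1 library (adjusted p up to 0.0709, 0.0908 and 0.0711). FOS and ATF3 stand both in this list and among the immediate early genes, and 17 of the 449 genes in the human lists stand in more than 1 list. DUSP1 stands in the glucocorticoid and immediate early lists, ANGPTL4 in the glucocorticoid and hypoxia lists, and CXCL8 among the inflammatory genes and the macrophage ligands.

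The hypoxia response, the genes that the HIF transcription factors switch on at low oxygen, showed the highest share of changed members among the lists that rose. Of its 20 genes 16 rose and none fell (19 and 0 adjusted over the list alone), with a median log2 fold change of 1.00 (camera adjusted p = 2.55e-19, or 0.0696 with an estimated correlation). ADM, a vasodilator peptide, rose from 45.5 ± 20.6 to 215 ± 44.1 CPM (4.72-fold, adjusted p = 0.00391), NDRG1 from 233 ± 90.7 to 880 ± 134 CPM (3.78-fold, adjusted p = 0.00323). The angiogenic factor VEGFA rose from 182 ± 43.7 to 378 ± 66.7 CPM (2.08-fold, adjusted p = 0.00355). Of 18 glycolysis genes 4 rose and none fell (6 and 0 adjusted over the list alone; median 0.19; camera adjusted p = 7.21e-05, or 0.202 with an estimated correlation). These were hexokinase HK2 (18.7 ± 7.68 to 82.7 ± 20.5 CPM, adjusted p = 0.00391), phosphofructokinase PFKP (1.45-fold, adjusted p = 0.00522), the glucose transporter SLC2A1 (1.90-fold, adjusted p = 0.00631) and ENO2. SLC2A1 and ENO2 also stand in the hypoxia list, so that this result partly repeats that one.

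Genes of the cell cycle moved the other way. Of 24 S phase and DNA replication genes 21 fell and none rose (23 fell adjusted over the list alone; median −0.55; camera adjusted p = 2.46e-18, or 0.0824 with an estimated correlation). Among them were the flap endonuclease FEN1 (68.9 ± 15.2 to 42.8 ± 2.21 CPM, adjusted p = 0.00241) and the replicative helicase subunit MCM6 (89.4 ± 17.5 to 54.8 ± 6.06 CPM, adjusted p = 0.00252). Of 24 genes of mitosis and the G2/M transition 18 fell and none rose (23 fell adjusted over the list alone; median −0.56; camera adjusted p = 5.76e-15, or 0.130 with an estimated correlation). They included the cyclin CCNB1 (0.669-fold, adjusted p = 0.00631) and the mitotic kinesin KIF20A (0.638-fold, adjusted p = 0.00579). MKI67, the proliferation marker Ki-67, fell from 180 ± 38.5 to 120 ± 19.2 CPM (adjusted p = 0.0272), a call that ended in 5 of the 15 fits that left out 1 library (adjusted p up to 0.0797). Of 20 targets of NRF2, the antioxidant regulator that A549 cells carry in an active state through their KEAP1 mutation, 6 fell and none rose (10 fell adjusted over the list alone; median −0.30; camera adjusted p = 2.45e-06, or 0.130 with an estimated correlation). Among them were malic enzyme ME1 (0.711-fold, adjusted p = 0.00850) and the glutathione synthesis gene GCLM (0.781-fold, adjusted p = 0.0106). Cholesterol synthesis had 7 of 20 genes down and none up (12 down adjusted over the list alone; median −0.47; camera adjusted p = 2.89e-07, or 0.202 with an estimated correlation). Among them FDPS fell to 0.658-fold (adjusted p = 0.0111). Of the 13 protein-coding genes of the mitochondrial genome 5 fell and none rose (7 fell adjusted over the list alone; median −0.38; camera adjusted p = 9.94e-07, or 0.173 with an estimated correlation). MT-ND3, for example, fell from 1047 ± 141 to 720.1 ± 91.2 CPM (adjusted p = 0.00729). The nuclear genes of oxidative phosphorylation did not pass as a list (2 of 23 fell; camera adjusted p = 0.1003), although they did without no-stress replicate 5 (camera adjusted p = 0.0403), stress replicate 1 (camera adjusted p = 0.0207) or no-stress replicates 1 and 5 together (camera adjusted p = 0.0377).

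Interferon-stimulated genes were higher in 4 of the 5 stress tumours than in any no-stress tumour. Of 19 tested members 12 rose and none fell (17 rose adjusted over the list alone; median 1.39; camera adjusted p = 8.23e-12, or 0.130 with an estimated correlation). ISG15, a ubiquitin-like modifier, rose from 185 ± 87.9 to 589 ± 250 CPM (3.18-fold, adjusted p = 0.0223), IFI6 from 540 ± 246 to 1563 ± 585 CPM (2.89-fold, adjusted p = 0.0208) and the RNA sensor OAS1 2.22-fold (adjusted p = 0.0174). The calls of ISG15 and IFI6 ended without no-stress replicate 1 or stress replicate 1 (adjusted p up to 0.0656 and 0.0622) and that of OAS1 without no-stress replicate 1 (adjusted p = 0.0526). With replicate number as a block in the fit all 3 ended (ISG15 adjusted p = 0.0730, IFI6 0.0570, OAS1 0.0544). Of 9 tested genes of antigen presentation 3 rose and none fell (8 rose adjusted over the list alone; median 0.86; camera adjusted p = 6.59e-06, or 0.130 with an estimated correlation). B2M, the light chain of MHC class I, rose from 351 ± 55.2 to 675 ± 207 CPM (adjusted p = 0.0131). The levels of members of this list in the MHC region are uncertain, since 154 of the 181 protein-coding genes there had under 1 CPM in every library.

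Of 19 NF-kB target and inflammatory genes 9 rose and none fell (11 rose adjusted over the list alone; median 0.74; camera adjusted p = 4.26e-08, or 0.136 with an estimated correlation). The neutrophil chemokine CXCL8 stood at 188 ± 60.1 and 587 ± 212 CPM (3.12-fold, adjusted p = 0.00814), the cytokine IL6 at 12.6 ± 4.49 and 44.2 ± 11.4 CPM (3.51-fold, adjusted p = 0.00354) and the apoptosis inhibitor BIRC3 2.34-fold higher (adjusted p = 0.00679). Of 16 tested ligands that attract macrophages or act on them 7 rose and none fell (9 rose adjusted over the list alone; median 0.40; camera adjusted p = 1.54e-06, or 0.0696 with an estimated correlation). CSF1, the main growth factor of macrophages, rose from 95.1 ± 28.3 to 159 ± 18.7 CPM (1.67-fold, adjusted p = 0.0340), a call that ended in 6 of the 15 fits that left out 1 library (adjusted p up to 0.0907). CSF2 rose 3.71-fold from a low level of 0.603 ± 0.333 CPM (adjusted p = 0.0138). The monocyte chemokine CCL2 stood at 7.24 ± 1.70 and 10.7 ± 4.72 CPM (adjusted p = 0.175), and IL34 had too few counts to be tested. Of 20 genes of epithelial-mesenchymal transition 5 rose and none fell, also when adjusted over the list alone (median 0.34; camera adjusted p = 2.56e-04, or 0.0717 with an estimated correlation). They included the intermediate filament gene VIM (1.34-fold, adjusted p = 0.0291), whose call ended in 5 of the 15 fits that left out 1 library (adjusted p up to 0.0839). Of 9 alveolar and airway secretory genes 1, the mucin MUC1, rose (1.63-fold, adjusted p = 0.0391), a call that ended in 7 of those 15 fits (adjusted p up to 0.102). That list passed with camera adjusted p = 0.0335, or 0.280 with an estimated correlation, a call that was lost without no-stress replicate 1 or stress replicate 3 (adjusted p up to 0.181), without no-stress replicates 1 and 5 together (adjusted p = 0.179) and with fry (adjusted p = 0.0851). Lists that did not pass were p53 targets (3 up and 2 down of 19, camera adjusted p = 0.651), the unfolded protein and ATF4 response (3 up of 18, camera adjusted p = 0.769), epithelial junctions (1 up of 21, camera adjusted p = 0.470) and ribosomal proteins (none of 24, camera adjusted p = 0.637). Of the genes of leukocytes and stroma not expected in A549 cells, 7 of 25 were tested and none passed (camera adjusted p = 0.769, direction up, median −0.18). Among them DCN, a proteoglycan of fibroblasts, stood at 8.36 ± 6.42 and 22.9 ± 15.5 CPM (adjusted p = 0.143) and the endothelial gene PECAM1 at 15.8 ± 2.76 and 12.8 ± 2.75 CPM (adjusted p = 0.499).

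**Figure D2:**
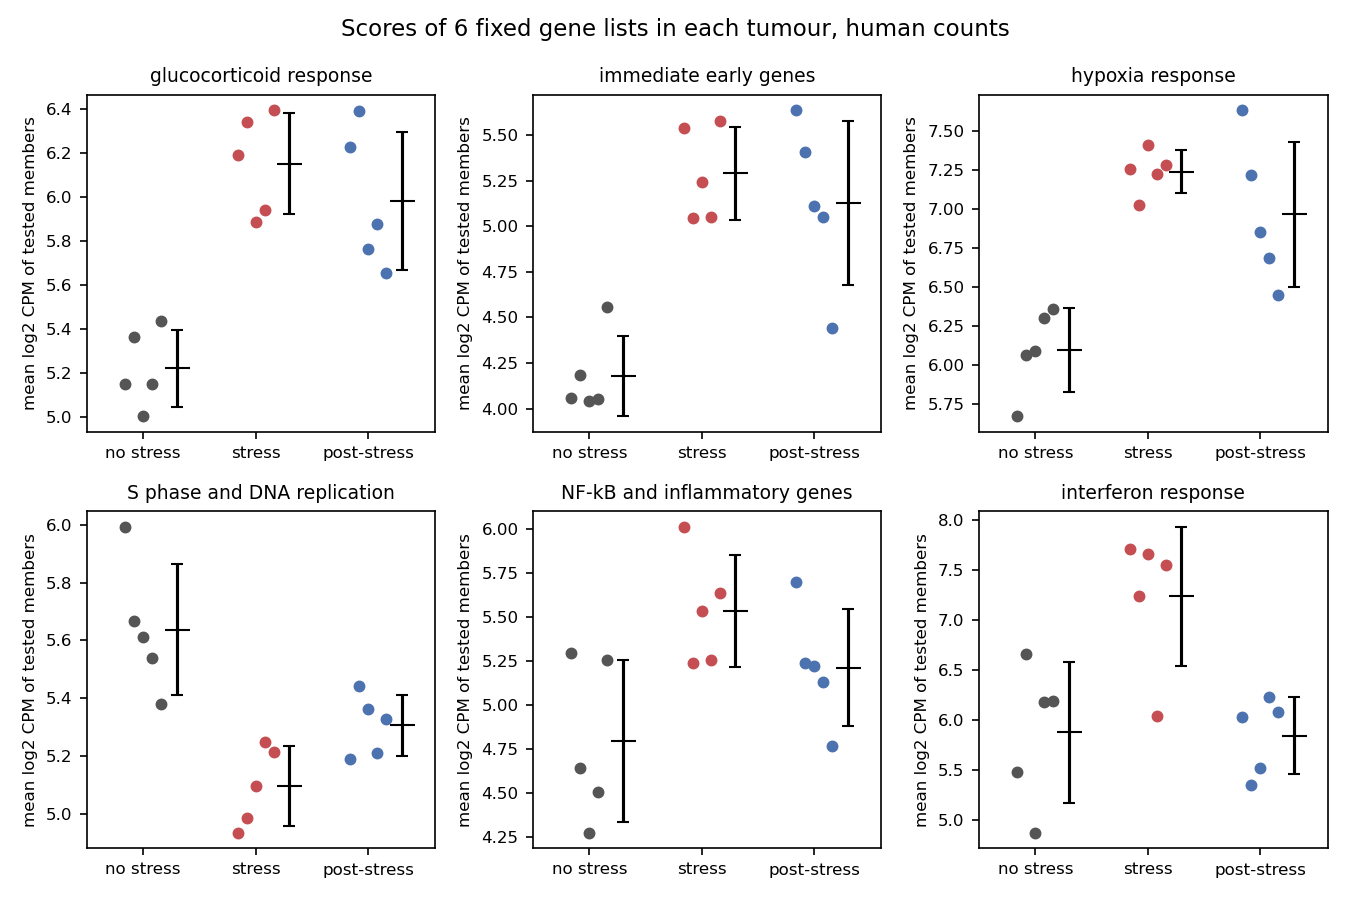
Mean log2 CPM over the tested members of 6 fixed lists of human genes in each of 15 tumours, by group. Points are single tumours, 5 per group, and the horizontal mark with its bar is the mean ± SD; the hypoxia score was 6.10 ± 0.27 without stress, 7.24 ± 0.14 with stress and 6.97 ± 0.47 with post-stress, and the interferon score of stress replicate 4, 6.04, lay apart from the 7.24 to 7.71 of the other stress tumours.

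The number of changed genes in this comparison depended on single libraries. It was 661 without no-stress replicate 1, 864 without no-stress replicate 3, 782 without stress replicate 1, 1043 without stress replicate 3 and 1072 without stress replicate 5, and 546 without no-stress replicates 1 and 5 together, a setting chosen after seeing the data because these 2 had the highest mouse share. Without a filter on low counts the calls of FKBP5, TSC22D3, CSF1, MKI67, NR4A3, ATF3, PCK1, IFI6, ISG15, MYCN and MUC1 ended (adjusted p from 0.0503 for ISG15 to 0.120 for MUC1). With limma-voom NR4A3 and MYCN did not pass (adjusted p = 0.0516 and 0.0672), whereas PER1 did (adjusted p = 0.0495), as it did with DESeq2's Wald test (adjusted p = 0.0293). The replicate block ended the calls of CSF1, MKI67, ATF3, PCK1, IFI6, ISG15, OAS1, VIM and CCDC190 (adjusted p from 0.0544 for OAS1 to 0.0925 for ATF3) and added PER1 (adjusted p = 0.0289). With the mouse share as a covariate CSF1, ATF3 and MUC1 did not pass (adjusted p = 0.0509, 0.0502 and 0.0509), and with only these groups in the fit ATF3 and ISG15 did not (adjusted p = 0.0502 and 0.0547). Without no-stress replicates 1 and 5 together the calls of FKBP5, TSC22D3, CSF1, MKI67, NR4A3, ATF3, PCK1, IFI6, ISG15, OAS1, B2M, VIM, MYCN and MUC1 ended (adjusted p from 0.0527 for MUC1 to 0.159 for MYCN). None of the 16 lists that camera called with its preset correlation between genes passed with an estimated correlation, where the smallest adjusted p was 0.0696. Fry, which does not compare a list with other genes, called 15 of these 16 (smallest adjusted p 3.98e-04), all but the alveolar and airway secretory genes. It was not run on other splits of the libraries.

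The comparison of post-stress with no stress asks the same of tumours whose hosts were restrained after transplantation. Expression of 130 of 15435 human genes changed, 92 upward and 38 downward (edgeR quasi-likelihood test, adjusted p under 0.05). Among the largest increases were DEPP1 (2.68 ± 1.43 to 18.2 ± 10.3 CPM, adjusted p = 0.0103), ANGPTL4 (36.4 ± 10.3 to 204 ± 142 CPM, 5.61-fold, adjusted p = 0.0223), STAC2 (7.50 ± 5.08 to 40.4 ± 33.9 CPM, adjusted p = 0.0478) and EGR1 (4.99-fold, adjusted p = 0.00658). Decreases included VASH2, a tubulin carboxypeptidase (8.71 ± 1.16 to 3.89 ± 1.09 CPM, adjusted p = 0.0137), and the retinoic acid receptor RARB (16.4 ± 2.29 to 7.51 ± 1.94 CPM, adjusted p = 0.00765). Also lower were the vitamin D receptor VDR (16.0 ± 1.96 to 8.67 ± 1.44 CPM, adjusted p = 0.00921) and BMAL1, a core transcription factor of the circadian clock (32.1 ± 2.97 to 16.8 ± 1.71 CPM, log2 fold change −0.93, SE 0.12, adjusted p = 0.00159). The calls of EGR1, RARB, BMAL1, VDR and DEPP1 held in each of the 15 fits that left out 1 library, whereas that of STAC2 ended in 13 of them (adjusted p up to 0.138), that of ANGPTL4 in 3 (adjusted p up to 0.0845) and that of VASH2 without no-stress replicate 1 (adjusted p = 0.0521).

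Of 22 glucocorticoid response genes 5 rose and none fell (14 rose and 1 fell adjusted over the list alone; median 0.71; camera adjusted p = 2.03e-13, or 0.0702 with an estimated correlation). FKBP5 rose to 273 ± 99.4 CPM (2.70-fold, adjusted p = 0.0353), IGFBP1 to 178 ± 64.5 CPM (2.44-fold, adjusted p = 0.0115) and MT1X 2.91-fold (adjusted p = 0.0468). The calls of FKBP5 and MT1X were lost in 8 and 9 of the 15 fits that left out 1 library (adjusted p up to 0.110 and 0.138). TSC22D3 stood at 157 ± 51.0 CPM (adjusted p = 0.103) and PER1 at 39.7 ± 22.9 CPM (adjusted p = 0.213). Of 16 immediate early genes 2 rose, EGR1 and FOS, and none fell (13 rose adjusted over the list alone; median 0.87; camera adjusted p = 4.30e-12, or 0.0702 with an estimated correlation). FOS rose 3.51-fold (adjusted p = 0.0389), a call lost in 9 of those 15 fits (adjusted p up to 0.129). Of the 15 cyclic AMP response genes 1, again FOS, rose (6 adjusted over the list alone; median 1.17; camera adjusted p = 1.95e-06, or 0.172 with an estimated correlation). Of 20 hypoxia genes 6 rose and none fell (18 rose adjusted over the list alone; median 0.78; camera adjusted p = 1.20e-20, or 0.0702 with an estimated correlation). NDRG1 rose to 841 ± 338 CPM (3.61-fold, adjusted p = 0.0103) and ENO2 to 129 ± 25.7 CPM (2.03-fold, adjusted p = 0.00159). ADM and VEGFA stood at 139 ± 71.9 and 307 ± 69.5 CPM and did not pass (adjusted p = 0.0520 and 0.0561). Of 18 glycolysis genes 3 rose, ENO2, HK2 and PFKP (6 adjusted over the list alone; median 0.25; camera adjusted p = 1.49e-08, or 0.172 with an estimated correlation). The calls of HK2 (adjusted p = 0.0394) and PFKP (adjusted p = 0.0137) were lost in 9 and 2 of those 15 fits (adjusted p up to 0.122 and 0.0533).

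Of 24 S phase genes 5 fell and none rose (16 fell adjusted over the list alone; median −0.33; camera adjusted p = 2.03e-13, or 0.186 with an estimated correlation). Among them FEN1 stood at 48.4 ± 3.22 CPM (adjusted p = 0.0373), MCM6 at 63.0 ± 5.33 CPM (adjusted p = 0.0468) and the replication initiation factor MCM10 at 10.4 ± 0.833 CPM (adjusted p = 0.0308). These 3 calls were lost in 9, 13 and 6 of the 15 fits that left out 1 library (adjusted p up to 0.0936, 0.137 and 0.101). No single gene passed with edgeR in 7 further lists that camera called, although DESeq2's Wald test called GCLM (adjusted p = 0.0349) and IL6 (adjusted p = 0.0127). These were mitosis and G2/M (median −0.25, camera adjusted p = 2.93e-06, or 0.419 with an estimated correlation), NRF2 targets (median −0.17, camera adjusted p = 0.00115, or 0.346 with an estimated correlation), cholesterol synthesis (median −0.13, camera adjusted p = 0.0377, or 0.696 with an estimated correlation) and mitochondrial-encoded genes (median −0.13, camera adjusted p = 0.0356, or 0.637 with an estimated correlation). The other 3, with higher values, were NF-kB and inflammatory genes (median 0.49, camera adjusted p = 1.89e-05, or 0.346 with an estimated correlation), macrophage-acting ligands (median 0.16, camera adjusted p = 0.009996, or 0.219 with an estimated correlation) and ribosomal proteins (median 0.26, camera adjusted p = 2.93e-06, or 0.419 with an estimated correlation). Adjusted over the list alone, 3 NRF2 targets fell and 2 inflammatory genes and 3 ligands rose. Of the epithelial-mesenchymal transition genes 1 rose (list median 0.19, camera adjusted p = 0.0148, or 0.219 with an estimated correlation). The calls of cholesterol synthesis, mitochondrial-encoded genes and epithelial-mesenchymal transition were lost in 4, 6 and 2 of those 15 fits (camera adjusted p up to 0.508, 0.256 and 0.0692).

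No interferon-stimulated gene passed in the post-stress group (0 of 19 with edgeR at adjusted p under 0.05, also adjusted over the list alone; median −0.19; camera adjusted p = 0.804). ISG15 stood at 195 ± 44.5 CPM (adjusted p = 0.952) and IFI6 at 543 ± 139 CPM (adjusted p = 0.996), beside 185 ± 87.9 and 540 ± 246 CPM without stress. B2M stood at 345 ± 55.6 CPM (adjusted p = 0.970), and antigen presentation did not pass as a list (0 of 9, median −0.20, camera adjusted p = 0.195). Without no-stress replicate 3 interferon response genes and antigen presentation passed downward (camera adjusted p = 0.0210 and 0.0459). CSF1, CCL2 and MKI67 stood at 131 ± 38.1, 7.14 ± 1.97 and 142 ± 25.9 CPM (adjusted p = 0.297, 0.983 and 0.29995). Further lists that did not pass were oxidative phosphorylation (camera adjusted p = 0.142), p53 targets (camera adjusted p = 0.577, direction up, median −0.06), the unfolded protein and ATF4 response (camera adjusted p = 0.136), epithelial junctions (camera adjusted p = 0.679), alveolar and airway secretory genes (camera adjusted p = 0.0807) and the leukocyte and stroma genes (camera adjusted p = 0.717, direction up, median −0.09). With 1 library left out, 3 of these passed. Oxidative phosphorylation passed upward without no-stress replicate 4 or post-stress replicate 4 or 5 (camera adjusted p from 0.00606 to 0.0133), alveolar and airway secretory genes upward without post-stress replicate 2 (camera adjusted p = 0.0112), and the unfolded protein and ATF4 response upward without post-stress replicate 5 (camera adjusted p = 0.0274).

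The count of 130 changed genes was less stable than the one for stress. It was 37 without no-stress replicate 1, 83 without no-stress replicate 2, 45 without no-stress replicate 3, 54 without post-stress replicate 1 and 51 without post-stress replicate 2, 49 with only these groups in the fit, and 38 with the mouse share of counts as a covariate. The covariate ended the calls of FKBP5, IGFBP1, ANGPTL4, MT1X, FOS, NDRG1, HK2, PFKP, FEN1, MCM6, MCM10, DEPP1 and STAC2 (adjusted p from 0.0584 for PFKP to 0.166 for STAC2). The replicate block, with which 57 genes passed, ended those of ANGPTL4, MT1X, FOS, NDRG1, HK2, PFKP, FEN1, MCM6, MCM10, DEPP1, STAC2 and VASH2 (adjusted p from 0.0524 for VASH2 to 0.124 for HK2) and added TSC22D3 (adjusted p = 0.0480). With only these groups in the fit IGFBP1, ANGPTL4, MT1X, FOS, NDRG1, HK2, FEN1, MCM6, MCM10, DEPP1 and STAC2 did not pass (adjusted p from 0.0511 for MT1X to 0.122 for STAC2). Without a filter FKBP5, MT1X, FOS, HK2 and STAC2 did not pass (adjusted p from 0.0594 for FKBP5 to 0.0845 for MT1X), nor did MCM6 and MCM10 with limma-voom (adjusted p = 0.0607 and 0.0541). ADM and VEGFA passed with limma-voom (adjusted p = 0.0231 and 0.0463), and ADM, VEGFA and TSC22D3 with DESeq2's Wald test (adjusted p = 6.36e-04, 0.00152 and 0.00256). None of the 14 lists called with the preset correlation passed with an estimated one (smallest adjusted p 0.0702). DESeq2's Wald test called 504 genes, and 32 passed without no-stress replicates 1 and 5 together, the setting chosen after seeing the data. That setting ended the calls of FKBP5, ANGPTL4, MT1X, FOS, HK2, PFKP, FEN1, MCM6, STAC2, VASH2 and VDR (adjusted p from 0.0608 for FEN1 to 0.230 for STAC2) and of the mitochondrial-encoded list (camera adjusted p = 0.0706).

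Many genes changed in the same direction in both restrained groups. Of the 92 genes higher with post-stress 80 were also higher with stress, and of the 38 lower genes 33 were also lower. ZMYND8 rose 1.53-fold with post-stress and 1.77-fold with stress, and INSIG2, which retains the cholesterol sensor SCAP in the endoplasmic reticulum, 1.71-fold and 1.92-fold. The synaptic scaffold gene PPFIA4 rose 3.07-fold and 3.29-fold, the methyltransferase NNMT 1.65-fold and 1.56-fold, the mitophagy receptor BNIP3L 1.63-fold and 1.76-fold, and NAB2, a corepressor of EGR1, 1.82-fold and 2.02-fold. BMAL1 fell to 0.525-fold and 0.522-fold and VDR to 0.542-fold and 0.521-fold. The covariance of the log2 fold changes of all 15435 genes was 0.0820 (r = 0.677 across genes, which are not independent replicates), against 0.0283 (r = 0.495) simulated for unchanged groups with the same controls, a difference of 0.0537. With the 5 controls split between the comparisons into 2 and 3, the mean covariance over 20 splits was 0.0524 (0.0289 to 0.0681; mean r = 0.347). Over 10 such splits the comparisons shared a median of 1 higher and 1 lower gene, where post-stress called a median of 1 higher and 1.5 lower genes.

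Stress and post-stress were compared directly to ask whether the time of restraint, and perhaps its length, made a difference. The difference passed for 6 of 15435 genes (edgeR quasi-likelihood test, adjusted p under 0.05), and 1716 had an unadjusted p under 0.05. Higher with stress were MDK, the heparin-binding growth factor midkine (20.5 ± 3.74 against 7.19 ± 2.07 CPM, 2.85-fold, adjusted p = 0.0242), and the mitochondrial phosphatase gene PPM1K (8.70 ± 2.09 against 2.71 ± 1.02 CPM, 3.21-fold, adjusted p = 0.0290). So were the histone H2B genes H2BC4 (8.08 ± 2.12 against 3.06 ± 0.856 CPM, adjusted p = 0.0242) and H2BC12 (34.9 ± 3.51 against 21.98 ± 2.97 CPM, adjusted p = 0.0290). The ceramide kinase gene CERK (37.2 ± 5.31 against 56.6 ± 5.17 CPM, adjusted p = 0.0242) and RAB26, a GTPase of secretory vesicles (7.41 ± 1.06 against 12.8 ± 1.78 CPM, adjusted p = 0.0290), were lower. MDK, PPM1K and H2BC4 also rose against no stress (adjusted p = 0.00391, 0.00412 and 0.0169), H2BC12 did not pass (adjusted p = 0.0809), and CERK and RAB26 fell (adjusted p = 7.95e-04 and 0.00342). The rise of H2BC4 did not pass without no-stress replicates 1 and 5 together (adjusted p = 0.0747). Histone genes of this family are close copies of each other and their levels are uncertain. No member of the interferon list passed over all genes with edgeR, although DESeq2's Wald test called IFI6 (adjusted p = 0.00220), ISG15 (adjusted p = 0.0115) and OAS1 (adjusted p = 0.00349). With edgeR 17 of 19 were higher with stress when adjusted over the list alone (median 1.58; camera adjusted p = 1.65e-21, or 0.110 with an estimated correlation). All 9 tested antigen presentation genes were higher adjusted over the list alone (median 0.97; camera adjusted p = 7.81e-13, or 0.0990 with an estimated correlation), with B2M at 675 ± 207 against 345 ± 55.6 CPM (adjusted p = 0.1003 over all genes).

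Of the other lists 5 were higher with stress than with post-stress by camera with its preset correlation, of which fry called only the ligands (adjusted p = 0.0298). The ligands acting on macrophages had a median of 0.29 (camera adjusted p = 1.57e-05, or 0.0990 with an estimated correlation), inflammatory genes 0.25 (camera adjusted p = 3.22e-04, or 0.420 with an estimated correlation) and glucocorticoid response genes 0.20 (camera adjusted p = 0.0154, or 0.435 with an estimated correlation). Hypoxia genes had 0.14 (camera adjusted p = 1.33e-04, or 0.420 with an estimated correlation) and epithelial-mesenchymal transition genes 0.13 (camera adjusted p = 0.00880, or 0.329 with an estimated correlation). A further 7 were lower. Mitosis genes had a median of −0.29 (camera adjusted p = 1.92e-11, or 0.369 with an estimated correlation), cholesterol synthesis −0.30 (camera adjusted p = 5.00e-07, or 0.382 with an estimated correlation), S phase genes −0.21 (camera adjusted p = 1.27e-07, or 0.382 with an estimated correlation) and mitochondrial-encoded genes −0.23 (camera adjusted p = 2.57e-06, or 0.382 with an estimated correlation). Ribosomal proteins had −0.20 (camera adjusted p = 1.57e-05, or 0.435 with an estimated correlation), oxidative phosphorylation −0.16 (camera adjusted p = 5.98e-05, or 0.420 with an estimated correlation) and NRF2 targets −0.11 (camera adjusted p = 0.00163, or 0.420 with an estimated correlation). No member of these 12 lists passed over all genes with edgeR and its filter. DESeq2's Wald test called IGFBP1 (adjusted p = 6.09e-05), KIF20A (adjusted p = 0.0178), BIRC3 (adjusted p = 0.0248) and MT-ND3 (adjusted p = 0.0190) among the named members, and limma-voom IGFBP1 (adjusted p = 0.0481). Without a filter edgeR called KIF20A (adjusted p = 0.0158) and MT-ND3 (adjusted p = 0.0480). Adjusted over the list alone, 2 inflammatory genes and 1 glucocorticoid response gene were higher, and 4 mitosis, 3 mitochondrial-encoded, 1 oxidative phosphorylation and 1 cholesterol synthesis gene lower. The other 8 lists did not pass (camera adjusted p from 0.0754 for the cyclic AMP response to 0.985 for leukocyte and stroma genes). Of these the cyclic AMP response passed upward without no-stress replicate 2, 3 or 5, stress replicate 2 or 4, or post-stress replicate 1 or 2 (camera adjusted p from 0.00746 to 0.0498), and without no-stress replicates 1 and 5 together (camera adjusted p = 0.0289). Immediate early genes passed upward without stress replicate 2 or 4 or post-stress replicate 1 or 2 (camera adjusted p from 0.00597 to 0.0439). The p53 targets passed downward without stress replicate 5 or post-stress replicate 2 or 3 (camera adjusted p from 0.0170 to 0.0424).

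The direct comparison of genes rested on single libraries more than the other 2. The count rose from 6 to 189 without stress replicate 4, was 13 without no-stress replicate 2, 1 without post-stress replicate 5 and 0 without stress replicate 2, 3 or 5, or post-stress replicate 2 or 3. It was 1 with only these groups in the fit, 36 without a filter on low counts and 0 with the mouse share as a covariate or the replicate block, and DESeq2's Wald test called 203, among them B2M (adjusted p = 8.98e-04). The adjusted p of each of the 6 genes was 0.0841 with the covariate, and with only these groups in the fit MDK alone passed. With the replicate block none of the 6 passed (adjusted p = 0.164 for PPM1K and 0.117 for H2BC4, MDK, H2BC12, CERK and RAB26). Without no-stress replicates 1 and 5 together RAB26 did not pass (adjusted p = 0.0637). None of the 14 lists called with the preset correlation passed with an estimated one (smallest adjusted p 0.0990). The list calls lost without 1 library were those of glucocorticoid response (4 of 15 fits, camera adjusted p up to 0.160), oxidative phosphorylation and epithelial-mesenchymal transition (both without post-stress replicate 3, camera adjusted p = 0.0546 and 0.0682).

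**Figure D3:**
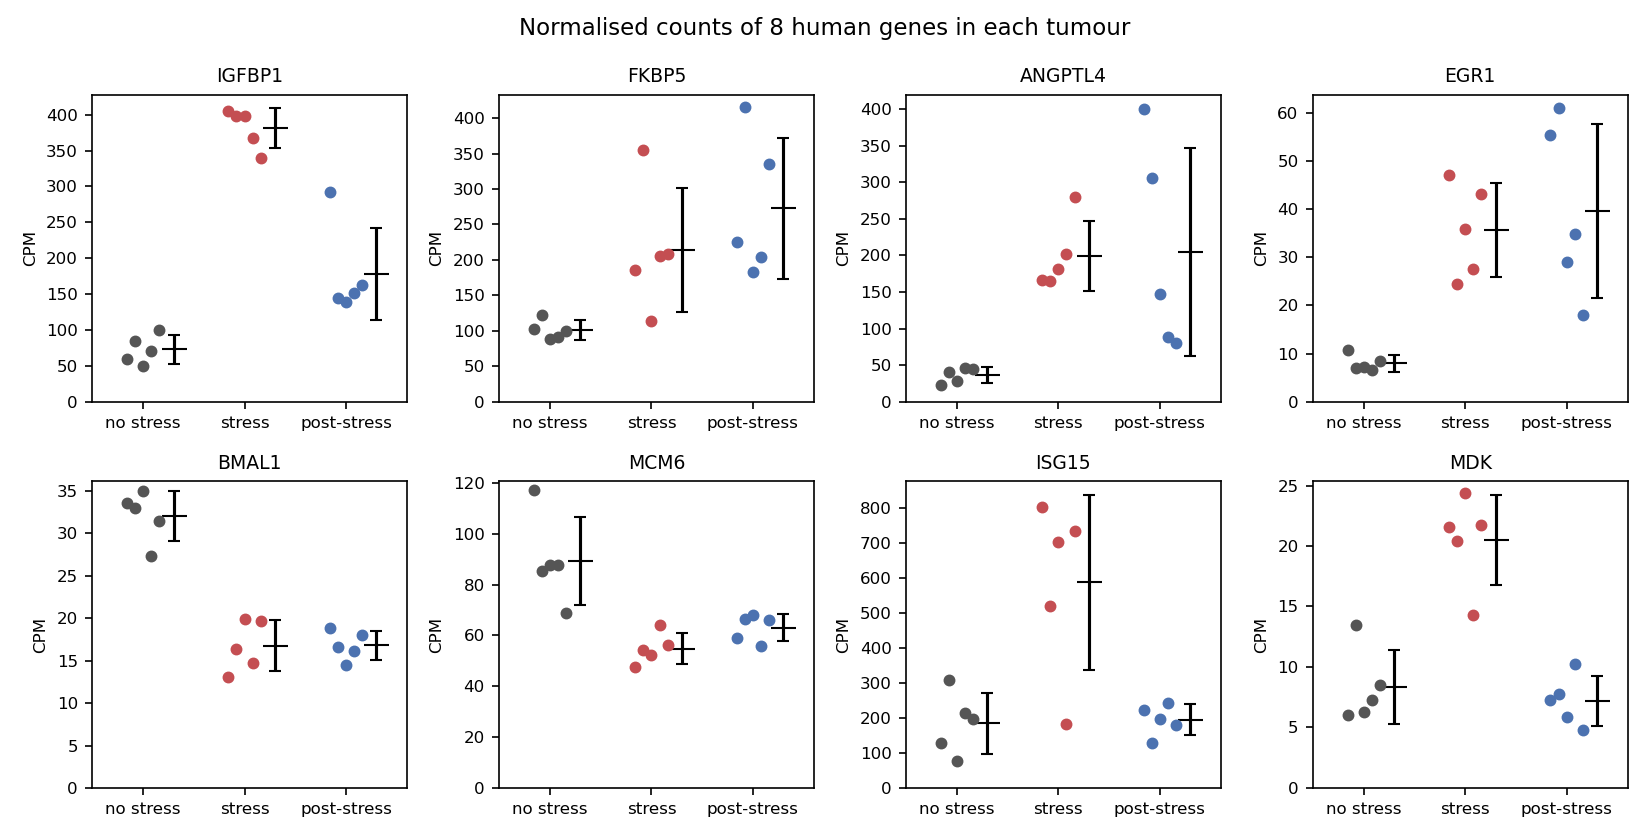
Normalised counts (CPM) of 8 human genes in each of 15 tumours, by group, with every axis starting at 0. Points are single tumours, 5 per group, and the horizontal mark with its bar is the mean ± SD; BMAL1 lay near 16.7 CPM in both restrained groups against 32.1 CPM without stress, while ISG15 was at 589 CPM with stress against 195 with post-stress and 185 without stress.

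In the genomic annotation of the human build GRCh38 the genes that lead these comparisons lie apart from each other. IGFBP1 spans positions 45888357 to 45893668 on chromosome 7 and ZMYND8 47209214 to 47356889 on chromosome 20. ENO2 spans 6913745 to 6923698 on chromosome 12, BMAL1 13276652 to 13387266 and MDK 46380756 to 46383837 on chromosome 11, and FKBP5 35573585 to 35728583 on chromosome 6.

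In the host compartment 32 of 13522 tested mouse genes changed with stress, 28 upward and 4 downward, and 5 changed with post-stress, all upward (edgeR quasi-likelihood test, adjusted p under 0.05). Of these 5, 3 were also higher with stress. The files list mouse genes by identifier only. ENSMUSG00000026358.14 rose from 20.5 ± 12.3 to 148 ± 49.5 CPM with stress (SD, n = 5; log2 fold change 2.85, SE 0.42, adjusted p = 0.0126) and to 146 ± 49.9 CPM with post-stress (adjusted p = 0.0360). ENSMUSG00000003545.4 rose from 3.58 ± 1.12 to 20.5 ± 16.2 CPM with stress (adjusted p = 0.0425). ENSMUSG00000032193.10 fell from 71.1 ± 16.3 to 27.0 ± 3.68 CPM with stress (log2 fold change −1.40, SE 0.19, adjusted p = 0.00913), and ENSMUSG00000006517.6 from 24.0 ± 5.36 to 13.7 ± 1.20 CPM (adjusted p = 0.0425). Between stress and post-stress no mouse gene passed with edgeR, DESeq2's Wald test or limma-voom, and 876 had an unadjusted p under 0.05 (edgeR; smallest adjusted p 0.743). The covariance of the fold changes of the 2 restrained groups was 0.0745 against 0.0571 simulated for unchanged groups with the same controls, and with the controls split it averaged 0.0168, between −0.0390 and 0.0517 over 20 splits. In data simulated at the depth of the 15 libraries, 38.8% of mouse genes changed 2-fold in the stress group were recovered, against 64.2% of human genes.

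The mouse counts of changed genes were small and moved with single libraries. The 32 genes with stress became 2 without no-stress replicate 3, between 12 and 19 without no-stress replicate 1, 2, 4 or 5, stress replicate 1, 2, 4 or 5, or post-stress replicate 2 or 3, 5 without no-stress replicates 1 and 5 together, 55 with the mouse share as a covariate and 170 with DESeq2's Wald test. The 5 genes with post-stress became 37 without post-stress replicate 5, 10 without stress replicate 3, 8 without no-stress replicate 1, 3 without post-stress replicate 3, 2 without no-stress replicate 5 and 0 without no-stress replicate 2, 3 or 4, stress replicate 4, or post-stress replicate 1, 2 or 4, 0 with only these groups in the fit, 14 without a filter on low counts and 157 with DESeq2's Wald test.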

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

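Chosen after the result was seen were the counts of splits without no-stress replicate 1 and with the mouse share as a covariate, the tests of single stress libraries behind the interferon genes, and of the MHC region. The other tests of this part were written before.

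The human response to stress comprised 1613 genes. Of 60 splits of the 10 libraries, only the real one gave as many, and the highest other split gave 128. The smallest share these splits allow is 1 of 60, so that chance is excluded at the share of 0.05 for this fit. A candidate explanation is that mouse reads counted on human genes follow the mouse share of each tumour. With that share as a covariate 1469 genes passed, 1398 of them among the 1613, and of 60 splits with the same covariate only the real one gave as many (highest other 392). The covariate did move other results, since it took post-stress from 130 to 38 genes. Another is that no-stress replicate 1, the library farthest from the others, carries the response. Without it 661 genes passed, and of 60 splits of the 9 libraries left into 4 and 5 only the real one gave as many (highest other 651, median of the others 0). The count with the covariate argues against the mouse share as the whole cause. Without no-stress replicate 1 another split called nearly as many genes as the real one, so that this count does not decide about that library. The fitted log2 fold changes of the 1613 genes had a median ratio of 0.991 to the reported ones with the covariate and 0.926 without this library (0.956 to 1.06 without each of the 9 other libraries), with the same sign for 1613 of 1613 in both. In both fits 100% of these genes kept sign and an unadjusted p under 0.05, but so they did without any of the other 9 libraries, and shares shuffled at random kept between 95.9% and 100%, so that this criterion, set beforehand, decides nothing alone. A part of no-stress replicate 1 stays open, and so does a part of the mouse share in single genes. For post-stress 1 of 60 splits gave as many as the real 130 human genes (highest other 1), under the share of 0.05. The lower counts of other settings, such as the 38 with the covariate, were not set against splits, so that chance is not firmly excluded. For stress against post-stress 3 of 60 splits gave 6 or more (highest other 51), and chance cannot be excluded. For mouse genes with stress 2 of 60 splits gave 32 or more, under the share of 0.05. Yet the highest other split gave 97, which may point to a structure of the samples other than the groups. The splits do not show what that structure would be. For mouse genes with post-stress 1 of 60 splits gave 5 or more (highest other 2), under the share of 0.05. This count is small and was 0 with only the groups compared in the fit, so that chance is not firmly excluded. For stress against post-stress all 60 gave 0 or more (real 0, highest other 0). For the lists, 5, 8 and 8 of 60 splits gave as many as the real 16, 14 and 14 (highest other 17, 15 and 16). The median of the other splits was 8, 9 and 10 lists. Chance cannot be excluded for any of the 3 real counts. Camera with its preset correlation thus called several lists in a typical other split. A small camera adjusted p of a single list with this setting is therefore not evidence alone.

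In the test of stress against post-stress 6 genes passed and, by camera with its preset correlation, 14 lists. None of these lists passed with an estimated correlation (smallest adjusted p 0.0990), and chance is not excluded for either count. The log2 fold changes were 1.40 for H2BC4, 1.51 for MDK, 1.68 for PPM1K, 0.67 for H2BC12, −0.60 for CERK and −0.79 for RAB26. List medians were 0.20 for glucocorticoid response, 0.14 for hypoxia, −0.16 for oxidative phosphorylation, −0.21 for S phase, −0.29 for mitosis, −0.11 for NRF2 targets, −0.30 for cholesterol synthesis, 1.58 for interferon response, 0.25 for inflammatory genes, 0.29 for macrophage-acting ligands, 0.13 for epithelial-mesenchymal transition, 0.97 for antigen presentation, −0.20 for ribosomal proteins and −0.23 for mitochondrial-encoded genes.

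The interferon genes were weighed among these. Left out singly, each stress library kept at least 92.4% of the median of 1.58, which argues against a single stress library carrying it. Without stress replicate 4, whose score was lowest, the median was 1.80 and 15 of 19 members passed over all genes. Mouse reads counted on human interferon genes may contribute: over 15 tumours the score had a Pearson r of 0.182 with the mouse share (permutation p = 0.514, adjusted p = 0.514) and a Spearman rho of 0.332 (p = 0.227, adjusted p = 0.454), and r was 0.542 without the 2 tumours farthest from the median share. This leaves that source open. In the same family of 2 relations, the leukocyte and stroma genes had r = −0.249 (permutation p = 0.369, adjusted p = 0.514), rho = −0.196 (p = 0.480, adjusted p = 0.480) and r = −0.0490 without those 2. The time of restraint, which the design names, also stays open.

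Low counts were seen in the MHC region. In this region of chromosome 6, 154 of 181 protein-coding genes (85.1%) had under 1 CPM in every library, against 301 of 858 (35.1%) on the rest of the chromosome, a ratio of 2.43. This is consistent with reads shared with alternative haplotype sequences not being counted. A biological explanation was not tested, so levels in this region are uncertain.

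In 24 of 318 groups of 5 tumours 1 library lay apart from the others, where chance gives about 15.9. Among list scores (mean log2 CPM) these were immediate early genes in no-stress replicate 5 (4.56, others 4.04 to 4.18), interferon genes in stress replicate 4 (6.04, others 7.24 to 7.71) and alveolar genes in no-stress replicate 1 (4.90, others 5.72 to 5.93). Epithelial-mesenchymal transition lay apart in stress replicate 5 (6.72) and post-stress replicate 3 (6.19), and mitochondrial-encoded genes in no-stress replicate 3 (10.6). In the no-stress group single genes lay apart in replicate 2 (PER1, 31.7 CPM), replicate 5 (FOS, 42.3 CPM; ADM, 81.7 CPM) and replicate 1 (FEN1, 95.2 CPM; KIF20A, 52.3 CPM). In the stress group they did in replicate 1 (CCL2, 18.9 CPM; NR4A3, 13.9 CPM; ATF3, 67.5 CPM), replicate 4 (KIF20A, 28.9 CPM; B2M, 314.9 CPM) and replicate 2 (LOXL2, 78.2 CPM). In the post-stress group they did in replicate 1 (IGFBP1, 292 CPM; PFKP, 285 CPM; SLC2A1, 942 CPM; KIF20A, 26.1 CPM; NAB2, 39.8 CPM), replicate 3 (ME1, 85.8 CPM) and replicate 2 (STAC2, 100.1 CPM).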

How the results depend on the processing

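The tests were planned except the fits without no-stress replicates 1 and 5 together, chosen after seeing their mouse shares. Results below differ from the reported counts by over 1.5 times, and the cause was not tested. For human genes changed with stress (1613) the count was 990 with the replicate block, 243 at a log2 fold change of at least 1 and 546 without both replicates. For post-stress (130) it was 504 with DESeq2's Wald test, 49 with only the groups compared, 57 with the replicate block, 38 with the mouse share as a covariate (36 of them among the 130), 33 at a log2 fold change of at least 1 and 32 without both replicates. For stress against post-stress (6) it was 203 with the Wald test, 36 without a filter, 1 with only the groups compared, 0 with the replicate block, 0 with the covariate and 3 at a log2 fold change of at least 1. For mouse genes with stress (32) it was 170 with the Wald test, 55 with the covariate and 5 without both replicates. For mouse genes with post-stress (5) it was 157 with the Wald test, 14 without a filter, 0 with only the groups compared, 28 with the replicate block and 3 without both replicates. With an estimated correlation camera called 0, 0 and 0 lists against 16, 14 and 14, and fry, which does not compare a list with other genes, called 6 for post-stress and 3 for stress against post-stress. With the controls split, the covariance of fold changes was 0.0524 for human and 0.0168 for mouse genes, against 0.0820 and 0.0745.

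Leaving out single libraries gave 661 to 1834 human genes for stress, 37 to 144 for post-stress and 0 to 189 for stress against post-stress, and 2 to 48, 0 to 37 and 0 to 0 mouse genes. The lists ranged from 15 to 17, 12 to 15 and 12 to 17. The difference in mouse share ranged from −3.27 to 0.370, −6.69 to −3.05 and 2.11 to 4.78 percentage points. Over all alternatives, values of named genes kept their side of the threshold 5323 times, lost it 377 times and gained it 59 times. For lists these numbers were 1209, 86 and 25, and no called direction turned. Values kept include those called in neither fit. With 1 library left out, calls ended at least once for 21 of 74 named genes with stress and 13 of 29 with post-stress. They did for 6 of 6 in stress against post-stress. These totals include named genes not reported here. No pairing by replicate number was seen: correlations between libraries of the same number ranged from −0.191 to 0.124 for human genes, and in 1 of 15 pairs of libraries from different groups the best match was the own number (−0.346 to 0.267 and 2 of 15 for mouse genes). In simulated data 38.8% of 2-fold changes of mouse genes were recovered, against 64.2% of human genes. The 28 mouse lists and the mouse share without mitochondrial-encoded genes were not run.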

Other observations

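The tests of this part were written before their results were seen, on lists made after BMAL1, NR1D1 and IGFBP1 had been noticed among the changed genes. BMAL1 fell in both restrained groups (log2 fold change −0.94 and −0.93). A candidate explanation is that the tumours were collected at, or shifted to, another phase of the circadian clock. Then the other clock genes would move together. Of 11 listed 10 were tested, and the score of in-phase minus antiphase genes differed by 0.123 for stress (exact permutation p = 0.587, adjusted p = 0.722) and 0.0729 for post-stress (exact permutation p = 0.722, adjusted p = 0.722), which leaves the explanation undecided. NR1D1, a repressor of BMAL1 named here after its values were seen, rose with stress (log2 fold change 1.88, edgeR adjusted p = 3.60e-04) and post-stress (1.27, edgeR adjusted p = 0.00924). With stress 3 of the 10 tested clock genes rose, 7 did not pass and none fell. Those that rose were NR1D2 (0.89, edgeR adjusted p = 0.00645), PER3 (1.11, edgeR adjusted p = 0.0149) and, from the antiphase genes, NFIL3 (1.00, edgeR adjusted p = 0.00260). With post-stress 0 of the 10 passed. The times of collection are not given in the sources used here.

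IGFBP1 and PCK1 are targets of FOXO factors, which insulin restrains, and lower insulin-type signalling in the tumour cells may explain their increase. The score of 17 other FOXO targets was 0.333 higher with stress (exact permutation p = 0.0397, adjusted p = 0.159) and 0.146 higher with post-stress (exact permutation p = 0.262, adjusted p = 0.524). It lay above all no-stress tumours in 2 of 5 stress and 0 of 5 post-stress tumours. Neither difference passed after adjustment over 4 tests, which leaves this open. With stress 8 of the 17 rose, among them CITED2 (log2 fold change 0.86, edgeR adjusted p = 0.00621) and CDKN1B (0.58, edgeR adjusted p = 0.00287), 9 did not pass and none fell. With post-stress 0 of the 17 passed.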
